A study of Mus musculus with 17 samples.

How the data were processed

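The deposited files hold 1 column of expected counts per library, the unit of RSEM, for 54146 genes, and a joint table of fragments per kilobase and per 1000000 (FPKM) by the authors. The file headers do not state the count unit; values not whole in 13.86 to 17.14% of the genes of a library and sums that differ between libraries fit expected counts. The submitters' processing notes name STAR 2.5.3, RSEM 1.3.0 and limma 3.38.3 with build mm10, and per the labels the libraries were made from total RNA with Qiagen RNeasy and Illumina TruSeq v4. The annotation release, the reads per library and any filter are not stated there. Reads were not aligned again. Groups were taken from the genotype and time labels of each sample.

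Expected counts were rounded to whole numbers before any test. The reference used for coordinates (GENCODE M21) is on GRCm38, the assembly that mm10 names, and 54079 gene IDs of the files are in it when the version suffix is dropped, 52480 with the suffix. Gene symbols are those of the reference by gene ID, or of the files where the reference lacks the ID, and 25575 of them differ from the files' own; 203 IDs share 101 symbols and were kept apart by ID. Every library had Xist counts and no Ddx3y counts, so all look female and no sex term was fitted. No library was a copy of another: between libraries of a group the chi-square per gene ran from 12.43 to 69.46.

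Genes were filtered with filterByExpr by group, which left 19557 genes. Library sizes were scaled with TMM factors (0.977 to 1.01). One edgeR 4.0.16 model with all 4 groups was fitted (estimateDisp at its defaults, glmQLFit with robust settings, glmQLFTest), with a common biological coefficient of variation of 0.152. The adjusted p of a gene is the two-sided quasi-likelihood F test p after Benjamini-Hochberg adjustment over all genes tested in a comparison, and a gene was called when it lay under 0.05. The comparisons were KO against WT at day 0 and at day 14, day 14 against day 0 in WT and in KO, and the difference between the KO effects of the days (the interaction). SE is the absolute log2 fold change divided by the square root of its F value. The 95% interval of a fold change was taken from SE with a normal quantile, so it is narrow for so few libraries. It covers the spread between libraries. The floor of 3 counts for a group without counts covers counting error only. CPM are averaged per group and given with the SD and n. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run on the same genes and libraries in R 4.3.3.

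Gene lists, 47 in all, were written from general knowledge of cell types and pathways. Each list with at least 5 genes tested was tested with camera on the edgeR fit at the preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists in a comparison. The same test with a correlation estimated from the residuals is given beside each call. Members are counted by the adjusted p over all genes, and by an adjustment over the list alone where the text says so. List scores of single libraries are means over members of the log2 CPM (prior count 2) minus its mean over the 17 libraries. The principal components of the log2 CPM carried 17.2, 12.8 and 10.6% of the variance and did not split the groups.

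Genes named by rule had an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and every library of one group above every library of the other; up to 10 each way with the largest fold change were named. Left out were predicted genes, genes with clone names (RP23-, RP24-, AC) or IDs as names, antigen receptor segments and pseudogenes. The CLIC genes were always named, and up to 4 members of each called list. Lists, comparisons, tests, thresholds, naming rules and most settings tried were fixed before the data were examined; leaving out genes with clone names was added to the naming rule afterwards. The surrogate variables (sva 3.50.0, 2 variables), the runs without genes near Clic4, and the tests by position, by pseudogene and of chance were added after the results were seen.

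Genes near Clic4 are those on chromosome 4 within 10 Mb of either end of Clic4 (ENSMUSG00000037242.8, 135213969 to 135272814, minus strand). For the test of pseudogenes, 1481 transcripts of tested pseudogenes were matched with BLAST 2.17.0 to transcripts of protein-coding genes. A parent was a match at 90% identity or more over at least 50% of the pseudogene's length. Of the pseudogenes not themselves near Clic4, 1249 had a parent. Tables were handled with pandas 2.3.3 and drawn with matplotlib 3.10.9.

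The code was tested on simulated data with 19557 genes and the group sizes of the study. In these data 200 of the better counted genes were changed and 2 gene lists were shifted. Every gene was drawn independently of the others. The simulation therefore does not show how the tests behave when genes vary together between libraries. The code recovered 38.7, 69.9 and 87.7% of genes changed by a log2 fold of 0.5, 1 and 2 at day 0, with 7 false calls. At day 14 it recovered 53.8, 75.0 and 97.3%, with 3 false calls. Recovery was 58.2, 77.8 and 93.4% between the days in WT, with 4 false calls, and 32.4, 72.3 and 95.5% in KO, with 6. For the interaction it was 15.8, 54.4 and 82.7%, with 7.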

Results

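Lungs of Clic4 knockout (KO) and wild-type (WT) mice were profiled by RNA sequencing at day 0 and day 14. Clic4 encodes chloride intracellular channel 4, a protein found in soluble and membrane-bound forms, and the series asks what it does in the host during metastasis of mouse mammary tumours. The strain label joins FVB to 6DT1, which is the name of a mouse mammary tumour cell line; what was done to the mice between the 2 days is not in the sample labels. There were 17 libraries: 4 WT and 2 KO at day 0, and 6 WT and 5 KO at day 14. They held 20607811 to 35743830 counts each. Mice were 6 weeks old at day 0 and 8 weeks at day 14, so day and age changed together. The numbers that end the sample titles run from 1 to 10 in WT and from 21 to 30 in KO, so any order those record follows genotype; the numbers that open the titles interleave the genotypes. Labels do not tie each library to an animal, and the design text of the series gives other group sizes than the labels, which were followed here; the p-values measure the spread between these samples, which may be technical.

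Clic4 was lower in every KO library than in every WT library. At day 0 it averaged 325.9 ± 2.17 CPM (counts per 1000000 counted; mean ± SD, n = 2) in KO and 943.3 ± 13.1 CPM (n = 4) in WT, a log2 fold change of -1.53 (SE 0.133, adjusted p = 1.93e-05) that left 34.6% of the WT level (95% interval 28.8 to 41.4%). At day 14 it averaged 335.8 ± 38.6 CPM (n = 5) against 1043 ± 154 CPM (n = 6), a log2 fold change of -1.64 (SE 0.09, adjusted p = 9.95e-09) that left 32.2% (28.5 to 36.4%). An exact two-sided permutation test of Clic4 gave p = 0.0667 at day 0, the smallest possible with 15 splits, and p = 0.00216 at day 14, the smallest possible with 462. Counts are gene totals, so they do not tell which exons gave the reads that remained in KO. Clic4 did not pass between the days: the log2 value was +0.15 in WT (SE 0.0924, adjusted p = 0.652) and +0.04 in KO (SE 0.12, adjusted p = 0.935). Of the 5 CLIC genes counted, Clic4 fell at both days and the other 4 did not pass over all genes. Clic6 came nearest at day 14 (+0.22, SE 0.0566, adjusted p = 0.211), and it rose when adjusted over the list alone; Clic1, Clic3 and Clic5 stood at +0.01, -0.04 and -0.04. The CLIC list was called lower at day 0 (adjusted p = 0.000474, and adjusted p = 0.195 with an estimated correlation) and at day 14 (adjusted p = 1.87e-06, and adjusted p = 0.0175 with an estimated correlation). Across all 5 comparisons, that day 14 call was the only one by camera's preset correlation that held with an estimated one; as the list holds Clic4 itself, it restates the knockout and tells nothing of the rest of the family.

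**Figure D1:**
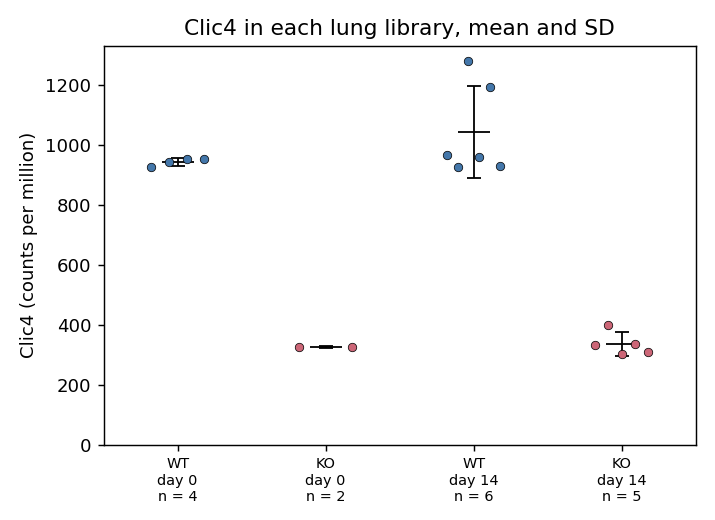
Clic4 CPM in each lung library, with WT in blue and KO in red at day 0 and day 14. Points are libraries, and bars show the group mean and SD.

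At day 0 the KO lungs differed from WT in 5 genes, of which 4 lie on chromosome 4, the chromosome of Clic4. Selenon, which encodes a selenoprotein of the endoplasmic reticulum, rose 1.52-fold (log2 +0.61, SE 0.0632, adjusted p = 0.000143), to 103.0 ± 11.3 CPM (n = 2) from 67.55 ± 0.703 CPM (n = 4). Pnrc2, a nuclear receptor coactivator that also takes part in mRNA decay, fell to 62.7% of WT (log2 -0.67, SE 0.11, adjusted p = 0.0343), at 51.87 ± 0.137 against 82.74 ± 6.52 CPM. Gm10036, a processed pseudogene of the ribosomal protein gene Rpl11, rose (log2 +0.79, SE 0.116, adjusted p = 0.0106; 8.688 ± 0.507 against 5.026 ± 0.279 CPM). Rsc1a1, a regulator of sodium-glucose cotransport, had no counts in either KO library and 9.22 ± 1.86 CPM in WT, which is at least 169.6-fold lower at a floor of 3 counts over the group (adjusted p = 0.0102). Rsc1a1 lies inside Ddi2, whose reads can be shared with it. Its loss was not seen at day 14, where it averaged 6.155 ± 1.62 CPM in KO and 5.58 ± 2.83 CPM in WT. The call of Rsc1a1 was lost without KO day 0 library 1 (adjusted p = 0.215) or 2 (0.164); that of Gm10036 without WT day 0 library 1 (0.0509) or 2 (0.0512) or KO day 0 library 1 (0.114) or 2 (0.189). That of Pnrc2 was lost without WT day 0 library 2, 3 or 4 (0.0827, 0.0884, 0.121), KO day 0 library 1 or 2 (0.409, 0.189), WT day 14 library 1, 5 or 6 (0.0574, 0.0512, 0.0588) or KO day 14 library 3 (0.0627). By edgeR 2 genes rose and 3 fell; DESeq2 called 26 genes and limma-voom 4, and without WT day 0 library 2 the count was 3, without KO day 0 library 1 or 2 it was 2.

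Lymphocyte genes stood lower in the day 0 KO lungs. The NK and cytotoxic list holds receptors and transcription factors of natural killer cells, and also granzymes, perforin and the chemokine gene Ccl5. It was called lower, with all 12 members at negative values and a median log2 of -1.12 (adjusted p = 1.78e-12, and adjusted p = 0.317 with an estimated correlation). When adjusted over the list alone 3 members fell. Its members include Tbx21 (-0.93, SE 0.26), Klrk1 (-1.31, SE 0.458) and Ncr1 (-1.23, SE 0.476). All 14 B cell genes, such as Fcrla (-1.60, SE 0.621) and the immunoglobulin heavy chain Ighm (-0.78, SE 0.333), were negative, with a median of -1.02 (adjusted p = 5.64e-11, and adjusted p = 0.317 with an estimated correlation). All 16 T cell genes were negative as well, among them the kinase Lck (-0.66, SE 0.293), with a median of -0.477 (adjusted p = 2.87e-06, and adjusted p = 0.496 with an estimated correlation). The proliferation list, genes of DNA replication and mitosis, had a median of -0.522 with all 24 members negative, Birc5 (-0.74, SE 0.345) and Plk1 (-0.59) among them (adjusted p = 7.09e-07, and adjusted p = 0.496 with an estimated correlation). Median values moved to -0.601 for NK and -0.589 for B cells without KO day 0 library 2, and to -0.329 for proliferation without WT day 0 library 1.

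Genes of alveolar type 2 cells and matrix stood higher in the day 0 KO lungs. All 15 genes of alveolar type 2 cells, which make surfactant, were positive, with a median of +0.245 (adjusted p = 2.7e-08, and adjusted p = 0.317 with an estimated correlation). Examples are the lipid synthase Fasn (+0.65, SE 0.197), the surfactant lipid transporter Abca3 (+0.28, SE 0.104) and the surfactant protein Sftpc (+0.26, SE 0.0985). The alveolar type 1 list was not called (7 of 15 positive, median -0.0504, adjusted p = 0.608). All 13 alveolar macrophage genes were positive too, with a median of +0.315 (adjusted p = 0.000403, and adjusted p = 0.496 with an estimated correlation). The fibroblast and extracellular matrix list had 19 of 22 members positive and a median of +0.163 (adjusted p = 2.56e-05, and adjusted p = 0.317 with an estimated correlation); elastin, Eln (+0.78, SE 0.208), rose when adjusted over the list alone. The adipose tissue list had a median of +0.923 (adjusted p = 7.09e-07, and adjusted p = 0.317 with an estimated correlation), with 3 members, Retn (+1.32, SE 0.421) among them, rising when adjusted over the list alone. The brown fat gene Ucp1 measured 24.16 CPM in KO day 0 library 2, 0.1059 CPM in library 1 and 0.06474 CPM on average in WT. Without KO day 0 library 1 the median of the type 2 list was +0.0654, that of the macrophage list +0.165 and that of the adipose list +1.39; without library 2 the type 2 median was +0.392, and the adipose call was lost (+0.269, adjusted p = 0.319). In all, 22 of 47 lists were called at day 0, 11 higher and 11 lower. Random regroupings of the day 14 libraries called a median of 16 lists and up to 25, and none were run at day 0.

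At day 14 the KO lungs differed from WT in 21 genes, 13 of them higher and 8 lower. Away from chromosome 4 Cemip, which encodes a hyaluronan-degrading protein, rose most (log2 +1.36, SE 0.197, adjusted p = 0.00324), to 2.928 ± 0.723 CPM (n = 5) from 1.136 ± 0.252 CPM (n = 6). The Wnt antagonist Dkk2 rose (2.558 ± 0.61 against 1.282 ± 0.196 CPM, adjusted p = 0.0461), as did the stress kinase Hipk2 (+0.93, SE 0.129, adjusted p = 0.00324; 68.3 ± 12.3 against 35.8 ± 4.37 CPM). Cdk19, a kinase of the Mediator complex (+0.55, SE 0.0744, adjusted p = 0.0018), the microtubule protein gene Map1b (+0.43, SE 0.0533, adjusted p = 0.000691) and the actin-capping Tmod2 (+0.37, SE 0.0543, adjusted p = 0.00324) rose as well. Hipk2 did not pass at day 0, where its value was -0.46 (adjusted p = 0.719). Sulf2, a heparan sulfate sulfatase picked out after its values were seen, rose (+0.29, SE 0.0549, adjusted p = 0.0477). Car4, a carbonic anhydrase of lung capillaries, rose (+0.28, SE 0.0471, adjusted p = 0.018; 230.7 ± 12.3 against 190.4 ± 8.53 CPM). The scavenger receptor Stab1 fell (-0.42, SE 0.0678, adjusted p = 0.0101; 154.5 ± 11 against 206.8 ± 9.49 CPM), and so did the lipoprotein receptor Scarb1 (-0.425, SE 0.0531, adjusted p = 0.000691; 102.4 ± 9.81 against 137.5 ± 2.1 CPM).

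Rhox5, Dynap and Gm7589 were close to absent from the day 14 KO lungs. Rhox5, a reproductive homeobox gene also expressed in many tumour cell lines, fell (log2 -3.20, SE 0.593, adjusted p = 0.0454), to 0.1421 ± 0.149 CPM (n = 5) from 1.378 ± 1.04 CPM (n = 6). Dynap, a dynactin-associated membrane protein, had 2 counts over the KO libraries and 79 over the WT libraries (-4.48, SE 0.705, adjusted p = 0.0207), and no counts at day 0 in either genotype. Gm7589, a second Rpl11 pseudogene, fell (-3.37, SE 0.349, adjusted p = 8.89e-05), with 0.06992 ± 0.0531 CPM in KO and 0.7976 ± 0.0876 CPM in WT, while Gm10036 rose (+0.61, SE 0.0838, adjusted p = 0.00196). Rpl11 itself did not pass (-0.03, SE 0.0444, adjusted p = 0.9). Dynap and both pseudogenes were picked out after their values were seen.

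DESeq2 called 109 genes at day 14, with all 21 among them, and limma-voom called 18, all of them shared. From the authors' FPKM, log2(FPKM + 1) and log2(FPKM + 0.1) each called 16 genes, 13 of them shared. Pnrc2, Stab1, Asap3 and Sulf2 lost their calls, Pnrc2 at day 0 too. Cemip, Slc30a2, Dynap and Dkk2 did not reach the FPKM filter and were not tested in those settings. With no filter, log2(FPKM + 1) called 15 genes, 13 of them shared. Slc30a2 was called there, but Cemip, Dynap, Dkk2 and Tmem222 were not, nor were Pnrc2, Stab1, Asap3 and Sulf2. Leaving out 1 library lost Car4 without KO day 14 library 2 (adjusted p = 0.0555) or 4 (0.0763), and Dynap without WT day 14 library 3 (0.0595) or KO day 14 library 1, 4 or 5 (0.0814, 0.0785, 0.056). Sulf2 was lost without any library but KO day 14 library 5 (0.0571 to 0.162), and Dkk2 without any but WT day 0 library 4 and KO day 14 libraries 2 and 5 (0.0535 to 0.131). Rhox5 was lost without any but WT day 14 library 4 and KO day 14 library 2 (0.05 to 0.124). The other genes away from chromosome 4 kept their calls whichever library was left out.

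**Figure D2:**
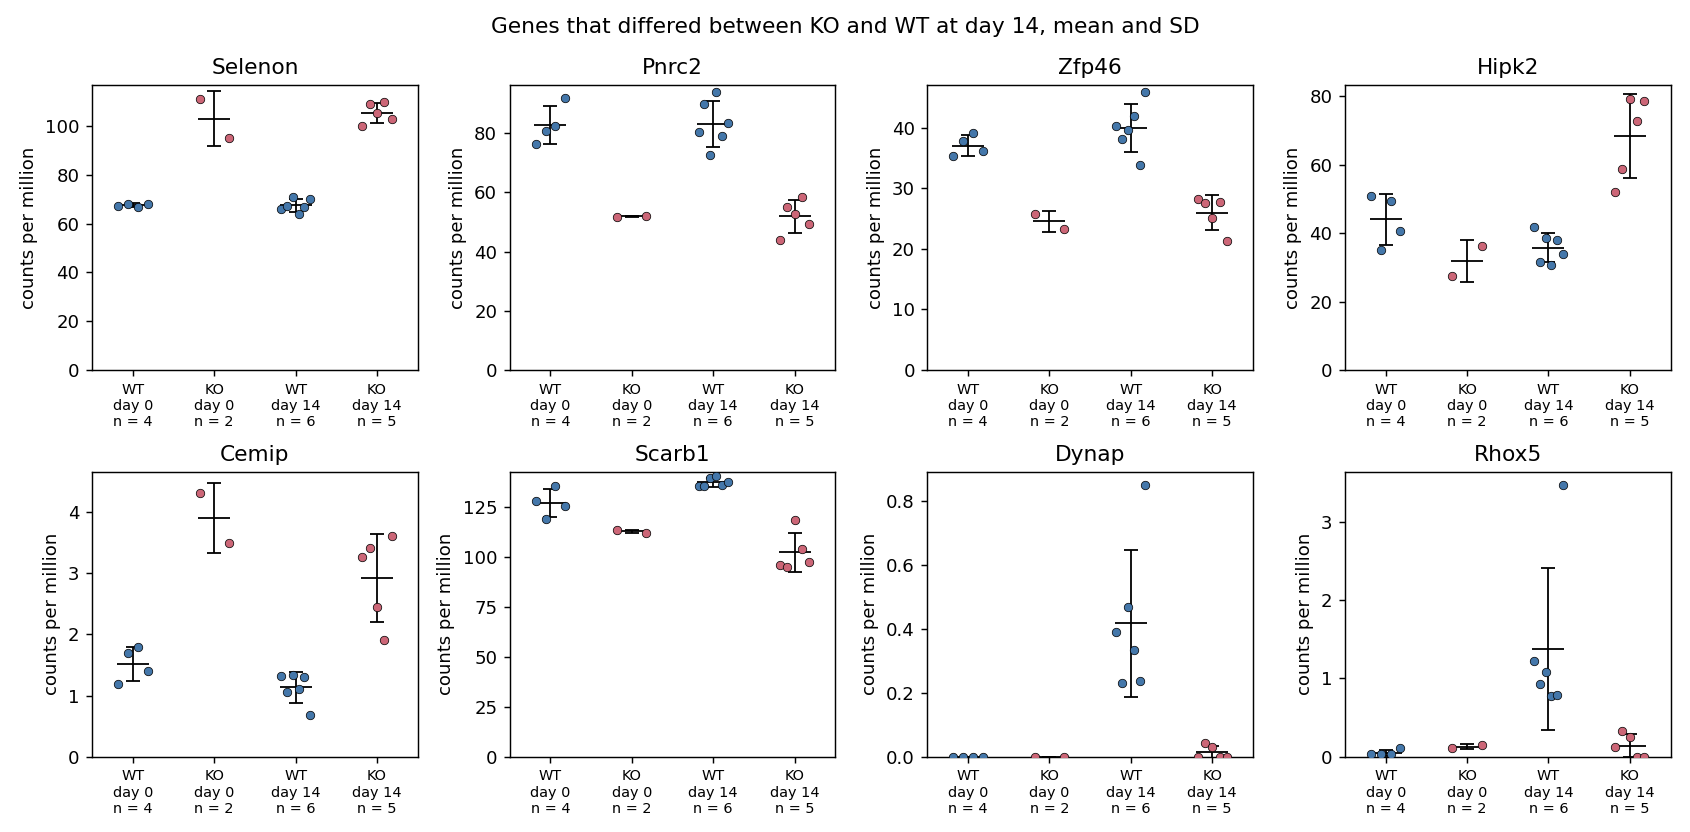
CPM of Selenon, Pnrc2, Zfp46, Hipk2, Cemip, Scarb1, Dynap and Rhox5 in each library, with WT in blue and KO in red. Points are libraries, and bars show the group mean and SD.

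Genes near Clic4 differed between KO and WT more often than genes elsewhere. At day 14 Selenon rose (+0.64, SE 0.045, adjusted p = 2.4e-07; 105.4 ± 4.04 CPM, n = 5, against 67.45 ± 2.6 CPM, n = 6) and Pnrc2 fell (-0.68, SE 0.0758, adjusted p = 0.000205), each as at day 0. The zinc transporter gene Slc30a2 rose (+1.44, SE 0.222, adjusted p = 0.00634), the Arf regulator Asap3 rose (+0.63, SE 0.118, adjusted p = 0.0449), the membrane protein gene Tmem222 rose (+0.36, SE 0.0657, adjusted p = 0.0429) and the zinc finger gene Zfp46 fell (-0.62, SE 0.0779, adjusted p = 0.000691). These 6 lie within 10 Mb of Clic4, where 6 of 308 genes were called, against 14 of 19230 elsewhere (two-sided Fisher test, p = 4.7e-07). The share of genes with an unadjusted p under 0.05 at day 14 was 30.3% within 5 Mb of Clic4, 14.3% from 5 to 10 Mb, 11.7% from 10 to 20 Mb, 8.95% on the rest of chromosome 4 and 8.67% on other chromosomes. At day 0 it was 18.3% within 5 Mb, 6.02% from 5 to 10 Mb, 3.76% from 10 to 20 Mb, 8.43% on the rest of chromosome 4 and 6.63% on other chromosomes, so only the nearest genes stood out. At day 0, 3 of 308 nearby genes were called against 1 of 19230 (two-sided Fisher test, p = 1.53e-05). The direction varied from gene to gene: of the 34 flanking genes listed, Selenon and Asap3 rose and Pnrc2 fell, and camera did not call the list (adjusted p = 0.195). Adjusted over the list alone 7 rose and 4 fell. Asap3 was lost without any library but WT day 14 library 1 and KO day 14 library 5 (adjusted p 0.0535 to 0.126), and Tmem222 without any but WT day 14 library 6, KO day 0 libraries 1 and 2 and KO day 14 libraries 3 and 5 (0.0571 to 0.124).

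**Figure D3:**
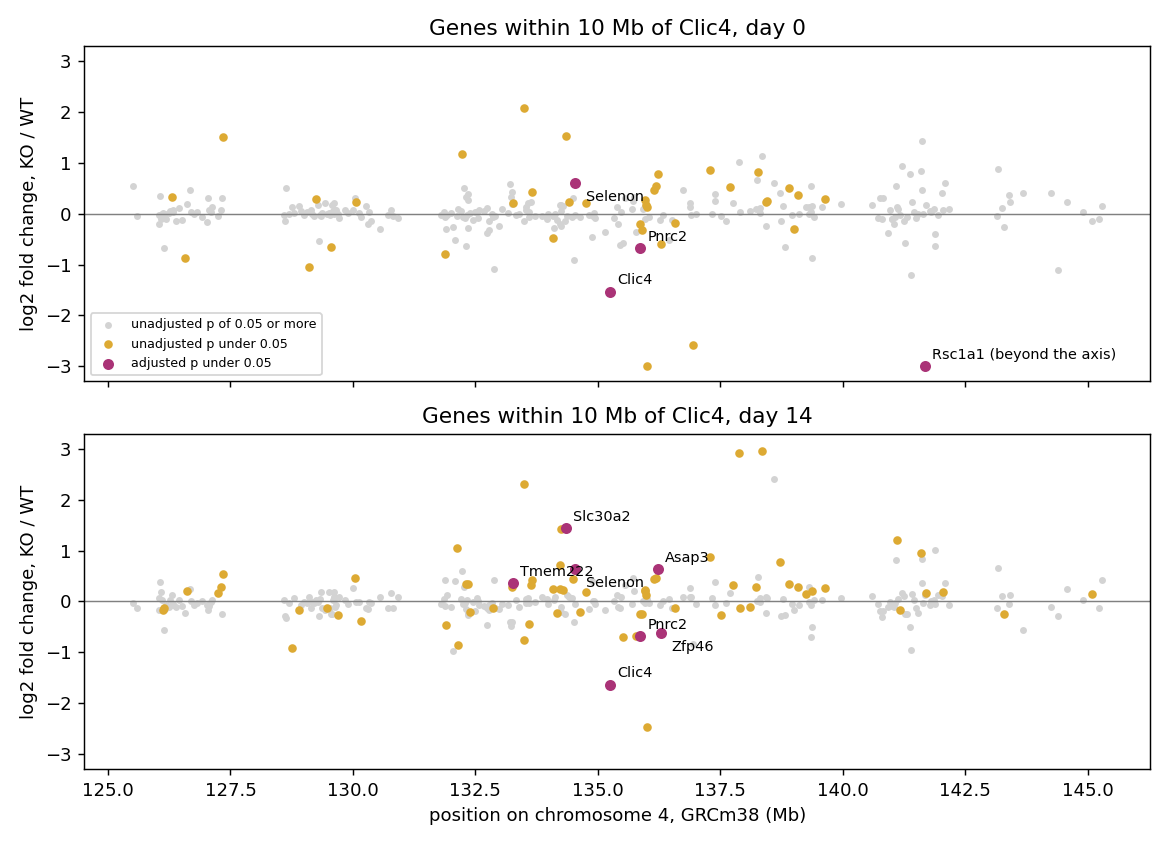
Log2 fold change of KO against WT for genes within 10 Mb of Clic4 by position on chromosome 4 in Mb, with day 0 and day 14 as separate panels and values beyond 3 either way drawn at 3. Each point is a gene, purple for adjusted p under 0.05, yellow for unadjusted p under 0.05 and grey for the rest.

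Airway, muscle and NK lists were called between the genotypes at day 14, with overlap between the libraries of both groups in each. The ciliated cell list, genes of motile cilia, was called higher with 14 of 15 members positive and a median of +0.236 (adjusted p = 2.95e-07, and adjusted p = 0.474 with an estimated correlation). Adjusted over the list alone 5 of its members rose, among them the dynein heavy chains Dnah9 (+0.32, SE 0.0735) and Dnah5 (+0.32, SE 0.0979). The list of heart and pulmonary vein muscle was called lower with 13 of 14 members negative and a median of -0.276 (adjusted p = 2.95e-07, and adjusted p = 0.474 with an estimated correlation); 5 fell when adjusted over the list alone, including the contractile genes Tnnt2 (-0.58, SE 0.138) and Myh6 (-0.56, SE 0.165). All 12 NK and cytotoxic genes were negative again, with a median of -0.538 (adjusted p = 3.94e-05, and adjusted p = 0.474 with an estimated correlation) and Eomes at -0.91 (SE 0.333). The dendritic cell list had a median of +0.125 (adjusted p = 0.00078, and adjusted p = 0.474 with an estimated correlation), and 3 members, the chemokine gene Ccl22 (+0.70, SE 0.139) among them, rose when adjusted over the list alone. Medians moved to -0.162 for muscle without WT day 14 library 5, to -0.245 for NK without WT day 14 library 3, and to +0.211, +0.197, +0.216 or +0.223 for dendritic cells without WT day 14 library 3 or 6 or KO day 14 library 4 or 5.

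Vessel genes at day 14 went both ways. Of 18 endothelial genes Car4 rose and 17 did not pass over all genes; adjusted over the list alone 4 fell, among them the caveolar diaphragm gene Plvap (-0.32) and the lipase anchor Gpihbp1 (-0.39). The list was called lower (median -0.0701, adjusted p = 0.0182, and adjusted p = 0.493 with an estimated correlation). The lymphatic endothelial list was called lower too (adjusted p = 0.0225, and adjusted p = 0.474 with an estimated correlation) although its median was +0.00802 and its mean -0.179; Lyve1 (-1.03, SE 0.232) and Flt4 (-0.29, SE 0.0708), receptors of lymphatic vessels, fell when adjusted over the list alone. The endothelial call was lost without WT day 14 library 1 (-0.0859, adjusted p = 0.051) or 5 (-0.0171, 0.0849) or KO day 14 library 5 (-0.055, 0.0973). The lymphatic call was lost without WT day 14 library 1 (0.0727) or 4 (0.0889) or KO day 14 library 2 (0.0683), and its median ran from -0.0793 without WT day 14 library 3 to +0.0418 without library 1. Nuclear RNAs that mark RNA quality were higher in the same KO group: all 8 were positive with a median of +0.32 (adjusted p = 0.00115, and adjusted p = 0.277 with an estimated correlation), and +0.114 without KO day 14 library 5. Adjusted over the list alone 3 of them rose. The same library had the highest erythroid and skeletal muscle scores, 1.9 and 1.65 log2 units above the mean of the 17 libraries. In all, 18 of 47 lists were called at day 14, 7 higher and 11 lower.

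**Figure D4:**
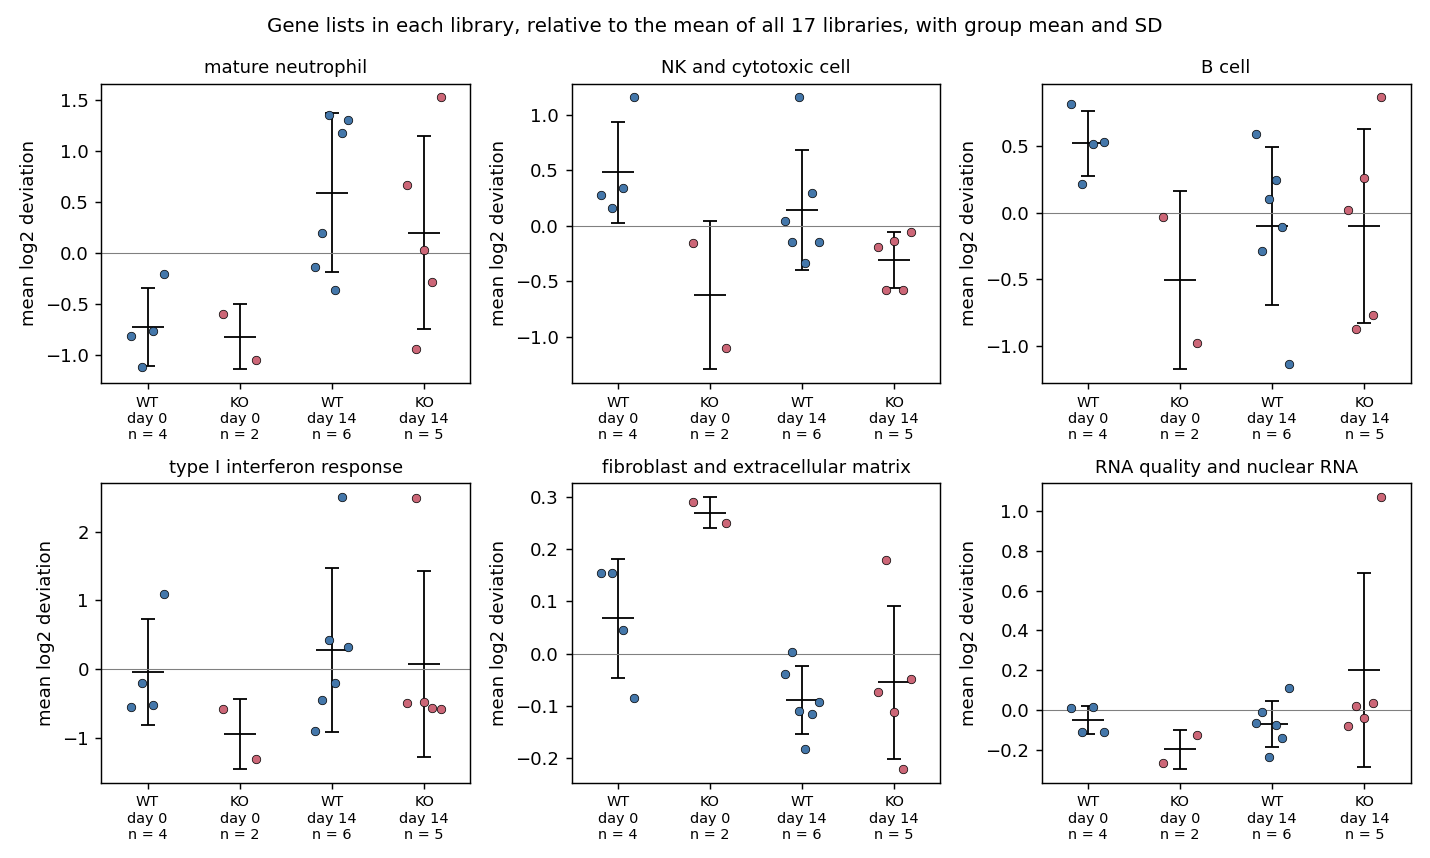
Mean log2 deviation of the members of 6 gene lists from their mean over the 17 libraries, with WT in blue and KO in red at day 0 and day 14. Points are libraries, and bars show the group mean and SD.

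Neutrophil genes stood higher in WT lungs at day 14 than at day 0, though WT day 14 library 4 (list score -0.362) lay below WT day 0 library 4 (-0.205). The mature neutrophil list had 15 of 16 members positive and a median of +1.55 (adjusted p = 1.21e-13, and adjusted p = 0.541 with an estimated correlation), and 12 of 16 rose when adjusted over the list alone, though the 16 did not pass over all genes. The 12 include the stefin Stfa2l1 (+2.35, SE 0.599), the chemokine receptor Cxcr2 (+1.86, SE 0.52) and the calcium-binding S100a9 (+1.98, SE 0.666). The granule genes of immature neutrophils Ngp (+2.59, SE 0.736) and Camp (+2.21, SE 0.658) rose when adjusted over their own list alone, which was called higher (median +0.704, adjusted p = 0.00661, and adjusted p = 0.541 with an estimated correlation). Genes of B cells were all negative (median -0.553, adjusted p = 2.31e-06, and adjusted p = 0.681 with an estimated correlation). Of 19 genes of cholesterol synthesis 17 were negative, with a median of -0.165 (adjusted p = 2.31e-06, and adjusted p = 0.681 with an estimated correlation) and Msmo1 at -0.40 (SE 0.115). The matrix list had 18 of 22 negative and a median of -0.149 (adjusted p = 9.82e-05, and adjusted p = 0.541 with an estimated correlation), with fibrillin, Fbn1, at -0.31 (SE 0.101). Markers of other tissue were higher in the same comparison: 11 of 12 adipose genes were positive (median +0.563, adjusted p = 6.04e-05, and adjusted p = 0.541 with an estimated correlation), as were all 14 genes of heart and pulmonary vein muscle (median +0.248, adjusted p = 7.26e-05, and adjusted p = 0.681 with an estimated correlation). The interferon gamma list had all 20 members positive and a median of +0.373 (adjusted p = 0.00256, and adjusted p = 0.79 with an estimated correlation), with the chemokine gene Cxcl9 at +1.68 (SE 0.592). Medians moved to -0.106 for cholesterol synthesis without WT day 14 library 6 to -0.0947 for matrix without WT day 0 library 2 and to +0.142 for muscle without WT day 14 library 5; the interferon gamma call was lost without WT day 14 library 5 (+0.0264, adjusted p = 0.283), and its median was +0.637 without WT day 0 library 4.

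Over single genes, edgeR called 0 between the days in WT, where the smallest adjusted p was 0.0574 and 1772 genes had an unadjusted p under 0.05; that is above the 978 expected of independent tests, but 9 of 100 groupings of the libraries, the real one counted, gave as many (highest other 2567). DESeq2 called 110 and limma-voom 1, Dynap. Without WT day 14 library 5, which had the highest type I interferon score of the series (2.51), 52 genes passed. Among these the homeobox gene Rhox5 (+4.83, SE 0.765, adjusted p = 0.0186), the protease inhibitor Serpinb2 (+2.01, SE 0.4, adjusted p = 0.0484), the endothelial receptor Gpr182 (+0.94, SE 0.134, adjusted p = 0.0186) and the interferon-induced Ifitm1 (+0.75, SE 0.127, adjusted p = 0.0322) rose. The zinc finger gene Zfp462 (-0.61, SE 0.0818, adjusted p = 0.0169) and Cd38, an NAD hydrolase of immune cells (-0.47, SE 0.0761, adjusted p = 0.0186), fell. Without WT day 14 library 6 the count was 2, Ifitm1 and Rhox5. Of 47 lists 14 were called, 8 higher and 6 lower.

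In KO lungs matrix and surfactant genes stood lower at day 14 than at day 0. The fibroblast and matrix list had 20 of 22 members negative and a median of -0.305 (adjusted p = 1.36e-11, and adjusted p = 0.132 with an estimated correlation). Adjusted over the list alone 6 fell, among them the collagens Col5a1 (-0.60, SE 0.118) and Col6a1 (-0.50, SE 0.105), fibrillin Fbn1 (-0.52, SE 0.129) and elastin Eln (-0.77, SE 0.199). All 15 alveolar type 2 genes were negative (median -0.3, adjusted p = 1.73e-09, and adjusted p = 0.4 with an estimated correlation), and 3 fell when adjusted over the list alone, Abca3 (-0.39, SE 0.1) among them. All 19 genes of cholesterol synthesis were negative (median -0.24, adjusted p = 1.73e-09, and adjusted p = 0.404 with an estimated correlation). Neutrophil genes had higher values: 15 of 16 were positive with a median of +1.39 (adjusted p = 1.93e-05, and adjusted p = 0.667 with an estimated correlation) and Cxcr2 at +1.74 (SE 0.705). No neutrophil gene rose by edgeR when adjusted over the list alone (4 of 16 had an unadjusted p under 0.05), but the day effects in KO and WT did not differ by test (median difference -0.0694, camera adjusted p = 0.287). KO day 14 library 2 (list score -0.945) lay below KO day 0 library 1 (-0.598). The interferon gamma list had all 20 members positive and a median of +1.11 (adjusted p = 3.95e-09, and adjusted p = 0.487 with an estimated correlation), with the guanylate-binding protein gene Gbp5 at +1.51. The type I interferon list had all 23 positive and a median of +1.71 (adjusted p = 0.000125, and adjusted p = 0.825 with an estimated correlation). RNA-quality transcripts moved with these groups (median +0.361, adjusted p = 0.0443, and adjusted p = 0.424 with an estimated correlation). KO day 14 library 2, with a type I interferon score of 2.5, bore on both interferon lists: without it the type I call was lost (+0.356, adjusted p = 0.118) and the gamma median was +0.581. Without KO day 0 library 1 the type 2 median was -0.159 and the RNA-quality call was lost (+0.21, adjusted p = 0.363), as it was without KO day 14 library 5 (+0.213, 0.0794), WT day 0 library 2 or 4 (0.0555, 0.051) or WT day 14 library 1, 4 or 5 (0.0502, 0.0547, 0.053).

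For single genes in KO, edgeR called 0 between the days; the smallest adjusted p was 0.0799, and 1770 genes had an unadjusted p under 0.05. DESeq2 called 97 and limma-voom 0. Without KO day 14 library 2 there were 12 genes: the collagens Col6a1 (-0.60, SE 0.0779, adjusted p = 0.01), Col6a2 (-0.67, SE 0.0924, adjusted p = 0.0132) and Col5a1 (-0.69, SE 0.107, adjusted p = 0.0403) fell, as did the basement membrane gene Lamb1 (-0.40, adjusted p = 0.0413). Without WT day 14 library 2 or 3 the count was 1, Rsc1a1, and without WT day 14 library 6 it was 2. Of 47 lists 16 were called, 9 higher and 7 lower.

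The KO effects at day 14 and day 0 differed by camera in lists of lymphocytes, dendritic cells and matrix. The B cell list had a difference of +1.01 (adjusted p = 2.88e-09, and adjusted p = 0.606 with an estimated correlation), its lower value in KO at day 0 not being met at day 14. The NK list had a difference of +0.518 (adjusted p = 0.00054, and adjusted p = 0.651 with an estimated correlation), and the dendritic list, genes of antigen presentation, +0.271 (adjusted p = 0.000161, and adjusted p = 0.606 with an estimated correlation). The matrix list had a difference of -0.126 (adjusted p = 0.00127, and adjusted p = 0.606 with an estimated correlation). For Hipk2 the difference was +1.40 (SE 0.234, adjusted p = 0.121), which did not pass by edgeR. DESeq2 and each FPKM setting called it, while limma-voom and every run with 1 library left out did not. The B cell value was +1.56 without KO day 0 library 1 and +0.634 without library 2; the NK value was +1.06 and +0.117 (adjusted p = 0.417) without these, +0.262 without WT day 0 library 4 and +0.82 without WT day 14 library 3. The dendritic and matrix values were +0.163 and -0.225 without KO day 14 library 2. For single genes edgeR called 0, with a smallest adjusted p of 0.0566, that of Rsc1a1. At unadjusted p under 0.05 there were 890 genes, fewer than the 978 expected of independent tests. DESeq2 called 9 and limma-voom 0. Rsc1a1 passed without WT day 14 library 2 or 3, when the count was 1. It also passed with a stricter filter, by DESeq2, in each FPKM setting and with surrogate variables. Of 47 lists 15 were called, 9 higher and 6 lower.

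Clic4, Selenon, Pnrc2 and Gm10036 were called in the same direction at both days, where independent lists would give 0.0013 genes up and 0.0012 down in both. These comparisons share no library, but 1 model fitted to all 4 groups gave both, so the lists are not fully independent. Clic4 is the targeted gene, and Selenon and Pnrc2 lie near it. Outside 10 Mb of Clic4, 1 gene was called at both days, Gm10036. Over all genes tested, the correlation of the KO effects at day 0 and day 14 was not clear of 0 (Pearson 0.134, jackknife SE 0.107, and -0.00163 with no filter; Spearman 0.172, jackknife SE 0.189), and 56.9% of genes had the same sign. Over the 309 genes within 10 Mb of Clic4, Clic4 included, the Pearson correlation was 0.4 and 67% had the same sign. The day effects in WT and in KO, which share no library either, had a Pearson correlation of 0.227, and 59.8% of genes had the same sign.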

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

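The tests of single libraries against their group were chosen after the results were seen. The interaction and its gene lists were fixed before the data were examined. Tests of single libraries against their own group, 171 in all over 21 genes and 35 lists, found 9 that stand out; chance gives about 1 in 20 groups, so about as many would be found by chance. Each value is a Dixon ratio, the gap between the extreme library and its nearest neighbour over the range of the group.

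For genes, Tmod2 in KO at day 14 had a ratio of 0.772, with library 1 lowest at 65.58 CPM and the next at 76.45 CPM. Rhox5 in WT at day 0 had a ratio of 0.93, with library 4 at 0.1075 CPM and the next at 0.03386 CPM. Rhox5 in WT at day 14 had a ratio of 0.832, with library 6 at 3.466 CPM and the next at 1.228 CPM. Leaving each of these libraries out is among the settings reported with the calls.

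For list scores (mean log2 deviation), the type I interferon list in KO at day 14 had a ratio of 0.97, with library 2 at 2.5 and the next at -0.485, and the interferon gamma list in WT at day 0 had 0.846, with library 4 at 0.393 and the next at -0.327. The proliferation list in WT at day 14 had 0.7, with library 2 at 0.601 and the next at 0.0182. The alveolar type 1 list in WT at day 14 had 0.762, with library 5 at 0.0808 and the next at 0.00597. The lymphatic endothelial list in WT at day 0 had 0.885, with library 3 at 0.0924 and the next at -0.0157. The RNA quality list in KO at day 14 had 0.898, with library 5 at 1.07 and the next at 0.0347.

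The interaction called 15 lists by camera although edgeR called 0 single genes there. At unadjusted p under 0.05 there were 890 genes, fewer than the 978 expected of independent tests. Values are the medians of the difference between the KO effects at day 14 and day 0, each with the adjusted p with an estimated correlation in brackets, and no list held under it. They were B cell 1.01 (0.606), adipose tissue -0.881 (0.606), proliferation 0.565 (0.778), unfolded protein response and heat shock -0.23 (0.606), alveolar type 2 -0.143 (0.608), dendritic cell 0.271 (0.606), NK and cytotoxic cell 0.518 (0.651), T cell 0.395 (0.79), interferon gamma 0.738 (0.79), glucocorticoid response -0.28 (0.606), fibroblast and extracellular matrix -0.126 (0.606), platelet and megakaryocyte 0.403 (0.77), alveolar macrophage -0.322 (0.79), type I interferon 0.962 (0.79) and RNA quality 0.396 (0.606).

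Most of these lists move when 1 of 2 KO day 0 libraries is left out. Without KO day 0 library 1 or 2 the B cell value was 1.56 or 0.634, adipose -1.35 or -0.147 (adjusted p = 0.417) and unfolded protein response -0.478 or 0.0513 (adjusted p = 0.911). T cell was lost without library 2 (0.283, adjusted p = 0.0798) and glucocorticoid response without library 2 (-0.27, 0.116) or KO day 14 library 2 (-0.189, 0.0719). Interferon gamma was lost without KO day 0 library 2 (0.382, 0.275) or KO day 14 library 2 (0.172, 0.165), and RNA quality without KO day 0 library 1 (0.273, 0.3). Alveolar type 2 was lost without KO day 0 library 1 (0.0121, 0.257), and platelet and megakaryocyte without WT day 0 library 2 (0.231, 0.0693) or KO day 0 library 1 (0.36, 0.0531). Calls that held but moved were alveolar type 2 (-0.0772 without WT day 0 library 2, -0.321 without KO day 0 library 2, -0.0902 and -0.227 without KO day 14 library 1 and 5), platelet (0.226 without KO day 14 library 5), proliferation (0.35 without WT day 0 library 1), RNA quality (0.251 without KO day 14 library 5), glucocorticoid response (-0.447 without KO day 0 library 1), interferon gamma (0.437 without WT day 0 library 4, 1.12 without WT day 14 library 5) and type I interferon (1.47 without KO day 0 library 1, 1.74 without WT day 14 library 5). Alveolar macrophage moved to -0.513 without WT day 0 library 1 and was lost without WT day 0 library 2 (-0.147, 0.134) or 3 (-0.218, 0.17), WT day 14 library 2 (-0.286, 0.059) or 3 (-0.22, 0.0541), KO day 0 library 1 (-0.158, 0.156) or KO day 14 library 2 (-0.289, 0.0776). Type I interferon turned without KO day 14 library 2 (-0.255, adjusted p = 0.926), and was lost without WT day 0 library 4 (0.456, 0.304), WT day 14 library 1 (0.774, 0.0997) or 2 (0.791, 0.0703) or 4 (0.81, 0.0505), or KO day 0 library 2 (0.663, 0.298). Whether day or genotype acts on these genes beyond single libraries stays untested, since KO has 2 libraries at day 0.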

How the results depend on the processing

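Each result was run again in up to 28 other settings including each library left out in turn. No paired analysis was possible because the labels tie no library of a genotype or day to one of another. The surrogate variables and the runs without genes near Clic4 were chosen after the results were seen. A sex term was not run since every library had Xist and lacked Ddx3y; the interaction was not run with only the groups compared, and camera was not run for DESeq2. Clic4 kept its call in 27 of 27 settings at each day, with a log2 fold change of -1.543 to -1.368 at day 0 and -1.707 to -1.567 at day 14. Of single genes past the threshold, 573 results stayed the same and 133 were weaker; of lists called, 2028 stayed, 245 were weaker and 7 reversed. The cause was not tested where a value moved. Where genes near Clic4 were left out, fewer genes were open to calling and the p-values were adjusted again over the rest.

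Genes called at day 0 (5) came to 26 by DESeq2, 14 with only the groups compared, 17 by log2(FPKM + 1) with no filter, 11 with surrogate variables, 1 with genes near Clic4 left out, and 2 to 7 with 1 library left out. Genes called at day 14 (21) came to 109 by DESeq2, 11 with genes near Clic4 left out, and 15 to 27 with 1 library left out. With genes near Clic4 left out, Rhox5, Dkk2 and Sulf2, which lie on other chromosomes, lost their calls too. Their unadjusted p-values were the same in that setting, so these calls depend on genes near Clic4 being part of the adjustment. Genes called between the days in WT (0) came to 3 by RLE normalization, 5 with no filter, 110 by DESeq2, 1 by limma-voom and 0 to 52 with 1 library left out. Those in KO (0) came to 97 by DESeq2, 2 with only the groups compared, 4 by log2(FPKM + 1), 4 by log2(FPKM + 0.1), 26 by log2(FPKM + 1) with no filter, 3 with surrogate variables and 0 to 12 with 1 library left out. For the interaction (0) they came to 1 with a stricter filter, 9 by DESeq2, 4 by log2(FPKM + 1), 3 by log2(FPKM + 0.1), 12 by log2(FPKM + 1) with no filter, 2 with surrogate variables and 0 to 1 with 1 library left out.

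Lists called with an estimated correlation came to 0 at day 0 (22), 1 at day 14 (18), 0 in WT (14), 0 in KO (16) and 0 for the interaction (15); with only the groups compared, 22 in WT. With 1 library left out they ran from 18 to 26, 13 to 20, 11 to 18, 13 to 22 and 10 to 21. The correlation of the KO effects at both days (Pearson 0.134) was -0.00163 with no filter, and 0.0846 to 0.169 (Spearman 0.0171 to 0.254) with 1 library left out. Genes called in the same direction at both days (4) came to 10 by DESeq2, 1 with genes near Clic4 left out and 2 to 5 with 1 library left out.

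List calls that turned direction by camera with 1 library left out were (medians) unfolded protein response and heat shock at day 0 (0.195; -0.145 without KO day 0 library 2, range -0.145 to 0.426) and in the interaction (-0.23; 0.0513 without KO day 0 library 2, from -0.478); erythroid at day 14 (0.553; -0.102 without KO day 14 library 5, up to 0.722); proliferation between the days in WT (-0.248; -0.0446 without WT day 0 library 1, from -0.439); and type I interferon in the interaction (0.962; -0.255 without KO day 14 library 2, up to 1.74). With surrogate variables the type I interferon calls turned, with medians of -0.0222 in KO between the days and 0.0294 in the interaction.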

Other observations

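The tests in this part were chosen after the results were seen, apart from the camera tests of lists, with all libraries or 1 left out. Granzymes d to g, serine proteases of activated cytotoxic and decidual cells, were picked out after their values were seen. Gzmd, Gzme, Gzmf and Gzmg had 0 counts over the libraries of day 0 in both genotypes, and at day 14 had sums of 52, 28, 79 and 98 counts over 6 WT libraries and 24, 16, 34 and 44 over 5 KO libraries. The prolactin family gene Prl2c3 was counted 608 times in WT and 89 times in KO at day 14, against 2 and 0 at day 0; single libraries held 342 of the WT and 75 of the KO counts. The mammary epithelial list had a median log2 value of 0.00146 between the days in WT (adjusted p = 0.762).

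KO day 14 library 5 had the fewest counts (20607811) and the largest share in its 20 most counted genes, 11.99%. The nuclear RNA Malat1 measured 3033 CPM in it and the small nuclear RNA Rn7sk 19.83 CPM. Mesothelial genes, markers of the lung surface, were called higher in KO at day 14 (median 0.227, adjusted p = 0.00135, and adjusted p = 0.474 with an estimated correlation), and the call was lost without KO day 14 library 2 (0.0762, adjusted p = 0.0648).

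Fblim1, Tmem82 and Eno1b, 3 genes picked out after their values were seen, were high in the same 6 libraries from all 4 groups. Fblim1, a filamin-binding protein gene, measured 55.78 CPM or more in WT day 0 library 4, WT day 14 library 6, KO day 0 library 1 and KO day 14 libraries 1, 3 and 4, and 33.92 CPM or less in the other 11. Eno1b, an enolase-like gene, measured at least 15.62 CPM in the same 6 and at most 2.422 CPM in the rest, and Tmem82, a membrane protein gene, at least 3.869 and at most 2.126 CPM.

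The libraries of a comparison were regrouped in 100 splits, of which 1 is the real grouping and is counted. The 21 genes called at day 14 were met or passed in 2 of 100 splits (highest other 25), so chance seldom gave such a count. The count holds Clic4 itself and 6 genes near it, and no splits were run without them. It therefore does not exclude chance for the genes away from Clic4, or for any single gene. Chance cannot be excluded for the 18 lists called (36 of 100, highest other 25). Nor can it for the 1750 genes at unadjusted p under 0.05 (17 of 100, highest other 2562). Between the days in WT 14 lists were met in 53 of 100 (highest other 20), so chance cannot be excluded for them. No splits were run at day 0, between the days in KO or for the interaction, so chance was not tested for the counts of lists called there. The count of 0 genes there is met in 100 of 100 by construction (highest other 14) and tests nothing.

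Genes near Clic4 differed between the genotypes as a set. With Clic4 itself counted, 73 had an unadjusted p under 0.05 in the real grouping. No other of the 100 splits reached that count (highest other 64), so chance seldom gave it. Chance is not fully excluded, since 100 of 462 possible splits were run and the test was chosen after the results were seen. The count does not test Selenon, Pnrc2 or any other single gene. Within 10 Mb 23.4% of genes had an unadjusted p under 0.05 at day 14, against 8.72% elsewhere (two-sided Fisher test, p = 1.93e-14). This argues against a batch that follows genotype as the whole cause. It does not exclude such a batch, as the test takes neighbouring genes as independent. In 1 of the other splits 40 genes near Clic4 were among 962 in all with an unadjusted p under 0.05. Loss of Clic4 acting on genes within 2 Mb alone cannot be excluded either. At day 14 the share at 2 to 10 Mb was 17.9% against 8.71% elsewhere (two-sided Fisher test, p = 1.47e-05), but no splits were run for that set. At day 0 the share from 5 to 10 Mb was 6.02%, against 6.63% on other chromosomes. A segment carried over from the strain in which the gene was targeted could change these genes and shift reads between genes and their copies; of the pseudogenes of nearby parents 12.5% had an unadjusted p under 0.05 against 5.07% of others (two-sided Fisher test, p = 0.126), with the 2 called copies of Rpl11 left out. All 3 were other copies of Rpl11 (3 of 5), and copies of other nearby parents gave 0 of 19 (two-sided Fisher exact test, p = 0.62), so the test cannot tell.

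Dynap and Rhox5 were counted in WT lungs at day 14 and close to absent in KO. Fewer reads in KO were already allowed for, since the calls were scaled to library size, so the counts here restate the calls and are no separate test. At the WT rate 56.7 Dynap counts would be met and 2 were found (upper bound 7.22). For Rhox5 it was 184 against 20 (upper bound 30.9). The bounds cover counting error only. Scaled to depth, the highest KO library lay below the lowest WT library, at 0.04163 against 0.2322 CPM for Dynap and 0.3331 against 0.7773 CPM for Rhox5. For Rhox5 the naming rule had asked for that. Fewer of the same cells in KO, with Prl2c3 as their measure, would give 11.6 Dynap counts (6.51 at the lowest ratio of any WT library) and 37.5 for Rhox5 (26.5); it would also give 14.3 Gzmg counts (9.37) where 44 were found (32.0 to 59.1), and Prl2c3 counts are held mostly by 1 KO library, so the test cannot tell. Such cells could be disseminated tumour cells, a hypothesis not tested here that sequence variants of the 6DT1 line would settle; loss of Clic4 in the lung itself lowering these genes also stays untested.

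NK and cytotoxic genes stood lower in KO at both days. Less blood in the KO day 0 lungs cannot be told from the erythroid list, whose median was -0.0397: its score differed by -0.0159 (SE 0.617, 95% interval -1.35 to 1.32), that of NK by -1.11 (SE 0.402, -1.98 to -0.241). A single library at day 0 cannot be excluded as a part of it, since the median was -0.601 without KO day 0 library 2. At day 14 the mean score differed by -0.455, and the exact two-sided permutation p = 0.0996 of 462 splits does not exclude chance; at day 0 it was p = 0.0667, the smallest possible of 15. Fewer NK cells in the KO lung, or less expression per cell, remain untested.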
